A study of Mus musculus with 62 samples.

How the data were processed

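PolyA RNA of mouse oviducts was sequenced from 54 libraries with a deposited table: 48 from 4 days after mating with a fertile male (dpc) or a vasectomised male (dpp), in 2 regions and with 3 libraries per group, and 6 from estrus, 3 per region. The labels state that oviducts were stored as 1 pair per animal but not that each library is a separate animal. The 8 superovulated samples belong to single-cell experiments, have no table among the files used here and were left out. Column headings of the deposited table use a P where the labels use dpp, and these were read as dpp.

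The deposited tables of the authors hold, for each gene and library, counts of reads, TPM (counts corrected for gene length and library total) and gene length. The deposited counts are whole numbers. The deposited TPM equal the counts divided by the deposited gene length and rescaled to one sum over the genes of each library, as checked on every library. Genes of low counts had been removed by the authors before deposit, and the highest count of each remaining gene is at least 51. The table of the 48 libraries holds 18462 genes and that of estrus 17241, of which 17136 are shared. Aligner, counting tool and annotation are not given in the sources used here. Of the 18462 identifiers, 18022 (97.6%) occur in the GENCODE M21 annotation of GRCm38, from which coordinates were taken.

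Total counts had a median of 49.7 M (39.7 to 71 M) in the 48 libraries and 41.8 M (36.4 to 60.3 M) in the 6 estrus libraries. With 3 libraries per group, p-values rest on a spread between libraries that is pooled over all groups of the fit. It is not the spread of the compared groups alone. Counts were simulated with the depth of each library and the spread of each gene over all groups. For dpc against dpp at day 0.5 in IU, 87% of 100 genes changed 2-fold and 98% of 100 changed 4-fold were called. Among the unchanged of the 18443 genes run there were 13 false calls. A further 16 genes, raised 1.5-fold for the list test, were left out of that count. The changed genes were drawn only from those of higher mean counts, and genes were simulated independently of each other.

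Counts were fitted in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM scaling, quasi-likelihood F test), in 1 model of 16 groups for the 48 libraries (18443 genes tested) and in a model with the estrus groups for the 17136 shared genes. Before the data were examined, limma-trend on log2(TPM + 1) had been planned on the assumption that the tables held TPM only. They also hold counts, so edgeR was used and limma became an alternative. P-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, with a threshold of 0.05. Standard errors are the absolute log2 fold change over the square root of F. Levels are the mean and SD of the deposited TPM. Principal components used the 1000 most variable genes on log2 CPM with a prior count of 2.

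Comparisons were dpc against dpp on each day in each region, the difference of these changes between regions, IU against IA in dpc and dpp (mean of 4 days) and in estrus, and successive days within each region of dpc. The comparison of 0.5 dpc with estrus had been planned only for the case that both tables hold the same genes. They share 17136 but differ in the rest, so the test was left out and levels are given side by side. A test on the shared genes was possible and was not made. The difference between day 1.5 and day 0.5 in IU was added after the counts of both days had been seen.

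Genes were named by a rule written before the data were examined: adjusted p under 0.05 and mean TPM of at least 5 in the higher group. No overlap between the groups was also required for dpc against dpp, successive days and regions in estrus. It was not applied to differences between regions. Nor was it applied to regions in dpc and dpp, though the written rule asked for it there within each day. Then followed the largest changes in each direction, leaving out genes with provisional names (8 for dpc against dpp, 10 for regions, 5 for successive days and for differences between regions). Up to 4 members of each list by smallest p were added. Genes of the circadian clock, those of single libraries that stood apart and a few further list members such as Myl9 were chosen after their values were seen. Before the data were examined, 41 lists of pathway genes and cell type markers were written, of which 40 (39 in the comparison with estrus libraries) had at least 4 measured members and were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. Calls "adjusted over the list alone" correct for the members of a list only.

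Alternatives were no filter on low counts, a filter at a TPM of 1 in 3 libraries, median-ratio size factors, limma-trend on log2(TPM + 1) and on log2(TPM + 0.1), DESeq2 1.42.0, a fit on only the groups compared, a replicate block, and leaving out each library in turn. The TPM filter, limma on log2(TPM + 1) as a complete test and DESeq2 were added after the files had been seen. In the fits without 1 library and in the other splits of the samples, the trended negative binomial dispersion was held at its value from all libraries.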

Results

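RNA sequencing of polyadenylated RNA measured gene expression in oviducts of C57BL6/J mice, taken as 2 pieces: infundibulum with ampulla (IA), the ovarian end where eggs are picked up and fertilised, and isthmus with uterotubal junction (IU), the uterine end that sperm enter first. Females had mated with fertile males (days post coitus, dpc) or with vasectomised males, which gives pseudopregnancy without sperm or embryos (days of pseudopregnancy, dpp). Tissue taken on 4 days, from day 0.5 to day 3.5, gave 16 groups of 3 libraries, 48 in all, and females in estrus gave 6 more libraries, 3 per region. Total counts per library had a median of 49.7 M in the 48 libraries (39.7 to 71 M) and of 41.8 M in the 6 estrus libraries (36.4 to 60.3 M). Values are fold changes on the log2 scale with their standard error, or means in TPM (counts corrected for gene length and library total) with their standard deviation (SD). Each rests on 3 libraries per group (n = 3). Here "higher" or "lower" refers to genes with an adjusted p under 0.05 in edgeR.

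Region separated the libraries most. The first principal component of the 1000 most variable genes held 78.0% of their variance and divided IA from IU, and the second held 8.7% and ran from day 0.5 to days 2.5 and 3.5. One IA library, 3.5 dpc replicate 2, lay between the 2 regions on the first component. It held 8.0 TPM of Hoxa9, a patterning gene of the IU end, against 0.0314 and 0.119 TPM in the other libraries of its group.

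**Figure D1:**
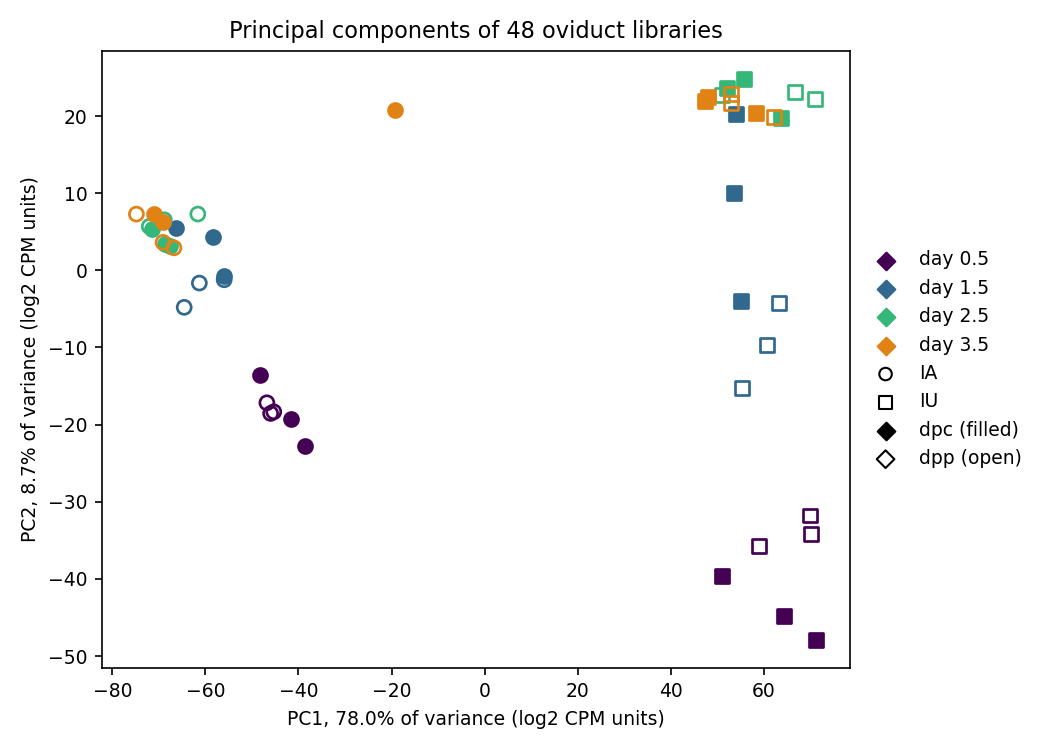
Each point is 1 of 48 libraries, placed by its first and second principal component (log2 CPM units, 78.0% and 8.7% of the variance of 1000 genes), with circles for IA, squares for IU, filled symbols for dpc, open symbols for dpp and colour for the day. IA libraries lie on the left and IU libraries on the right, day 0.5 lies lowest in both regions, and 1 IA library of 3.5 dpc lies between the regions.

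The first set of comparisons sets dpc against dpp on the same day, so mating with a fertile male against mating with a vasectomised male. Whether sperm, eggs or embryos lay in the pieces taken on a given day was not measured. At day 0.5 in IU, immediate early genes, which cells transcribe first after a stimulus, were higher after fertile mating: 9 of 16 measured genes were higher and 0 lower (12 higher when adjusted over the list alone). Fos, part of the AP-1 transcription factor, stood at 144 ± 35 TPM in dpc and 25.3 ± 3.51 TPM in dpp (2.52 ± 0.31, adjusted p = 3.3e-07), and the stress transcription factor gene Atf3 rose by 2.24 ± 0.19 (adjusted p = 2.63e-10). Hmox1 (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589, GRCm38), which encodes the haem-degrading enzyme haem oxygenase 1, stood at 405 ± 176 TPM against 41.6 ± 3.88 TPM (3.29 ± 0.22, adjusted p = 1.59e-12). Genes of glycolysis and lactate export were higher for 15 of 23 and lower for 1 (16 and 3 adjusted over the list alone). Among them were the lactate exporter gene Slc16a3 (1.55 ± 0.20) and the glycolytic enzyme genes Gapdh (0.79 ± 0.11), Pgam1 (0.77 ± 0.11) and Pfkp (1.04 ± 0.15). Both lists passed the gene list test (adjusted p = 1.32e-15 and 4.68e-11), with adjusted p = 0.0028 for immediate early genes and adjusted p = 0.146 for glycolysis with an estimated correlation.

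Among genes of inflammation in IU at day 0.5, NF-kB targets and regulators were higher for 8 of 22 and lower for 1 (13 and 1 adjusted over the list alone). Nfkbiz was up by 1.34 ± 0.23 and Ptgs2, the inducible prostaglandin synthase, by 1.72 ± 0.31, while Traf1, an adaptor of TNF receptors, fell by 1.42 on the log2 scale (SE 0.24). Of 25 cytokines and chemokines 4 were higher (9 adjusted over the list alone), Il1b among them at 14.6 ± 6.69 TPM against 2.50 ± 0.51 TPM (2.56 ± 0.43, adjusted p = 6.83e-05). Anti-inflammatory genes were higher for 7 of 21 (8 higher and 1 lower adjusted over the list alone), including the phosphatase gene Dusp1 (1.6 ± 0.20) and Zfp36, whose protein speeds decay of cytokine mRNA (0.70 ± 0.12). Neutrophil markers were higher for 6 of 16 (8 higher and 1 lower adjusted over the list alone). S100a9 stood at 23.6 ± 15.1 TPM against 1.3 ± 1.11 TPM (4.22 ± 1.04, adjusted p = 0.00598). Macrophage and monocyte markers were higher for 5 of 18 and lower for 1 (8 and 1 adjusted over the list alone), with the endotoxin co-receptor gene Cd14 up by 1.80 ± 0.21. The list test gave adjusted p = 6.01e-07 for NF-kB, 4.62e-07 for cytokines, 0.000828 for anti-inflammatory genes, 7.0e-04 for neutrophil and 0.000561 for macrophage markers. With an estimated correlation none passed (adjusted p = 0.234, 0.187, 0.341, 0.146 and 0.423).

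Smaller groups in IU at day 0.5 included interferon response genes, higher for 7 of 25 (13 adjusted over the list alone, list adjusted p = 6.01e-07, adjusted p = 0.423 with an estimated correlation). Antioxidant enzymes were higher for 5 of 22 and lower for 1 (8 and 2 adjusted over the list alone, list adjusted p = 7.0e-04, adjusted p = 0.423 with an estimated correlation). The peroxiredoxin-repairing Srxn1 was up by 0.82 ± 0.14. Matrix remodelling genes were higher for 5 of 21 (7 adjusted over the list alone, list adjusted p = 0.00144, adjusted p = 0.423 with an estimated correlation). The receptors for progesterone and oestrogen were lower, Pgr at 44.0 ± 2.30 TPM against 79.5 ± 5.46 TPM (−0.85 ± 0.13) and Esr1 at 125 ± 1.27 TPM against 188 ± 6.53 TPM (−0.58 ± 0.08). Other changes included the serine protease gene Prss28 (5.24 ± 0.85) and the potassium channel gene Kcnj16 (3.26 ± 0.50) upward. Downward went the channel subunit gene Kcne1 (−3.12 ± 0.43), the metalloprotease gene Adamts16 (−2.45 ± 0.30) and the retinoic acid binding protein gene Crabp2 (−2.47 ± 0.39). In all, 957 genes were higher and 1050 lower in dpc among 18443 tested (4297 at an unadjusted p under 0.05). Of the called genes, 261 and 187 changed by at least 2-fold.

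One library of the dpp group in IU, 0.5 dpp replicate 1, stood apart in Cyp11a1, a gene of steroid-making cells. It held 15.4 TPM against 0.0591 and 0.117 TPM in the other libraries of its group. Whether ovarian tissue was the source was not tested. Without that library, 679 genes were higher and 718 lower. Lists then gave immediate early genes higher for 9, glycolysis for 14 with 1 lower, NF-kB genes for 9 with 1 lower, cytokines for 3, neutrophil markers for 4, interferon genes for 3 and macrophage markers for 1 with 1 lower. Fitted on the 6 libraries of this comparison alone, 1183 genes were called.

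In IA at day 0.5, all 28 called genes were higher in dpc, and they included genes of macrophages and of the interferon response. Irf7, a transcription factor of the interferon response, stood at 40.8 ± 18.9 TPM against 14.8 ± 2.25 TPM (1.38 ± 0.26, adjusted p = 0.0107). Adgre1, which encodes the macrophage antigen F4/80, stood at 18.2 ± 10.3 TPM against 6.16 ± 0.95 TPM (1.50 ± 0.32, adjusted p = 0.0339). Cd52 and Nckap1l, both genes of leukocytes, rose by 1.45 ± 0.29 and 1.04 ± 0.19. Interferon response genes were higher for 2 of 25 (17 adjusted over the list alone, list adjusted p = 4.88e-18, adjusted p = 0.13 with an estimated correlation). Macrophage markers were higher for 2 of 18 (9 adjusted over the list alone, list adjusted p = 4.21e-12, adjusted p = 0.13 with an estimated correlation). Neutrophil markers were higher for 1 of 16 (3 adjusted over the list alone, list adjusted p = 4.97e-06, adjusted p = 0.057 with an estimated correlation), the receptor gene Csf3r (1.91 ± 0.40). At an unadjusted p under 0.05 there were 1717 genes.

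These calls in IA rested on few libraries: 11 genes were called without 0.5 dpc replicate 1 and 5 without 0.5 dpp replicate 1, and Irf7 and Nckap1l were lost in both. The edgeR count was 0 when only the 6 libraries compared were fitted. By limma on log2(TPM + 0.1) the count was 46 and by DESeq2 112. Of 10 splits of these 6 libraries, 3 called at least 28 genes, the real one included, and the highest of the others called 1307. Of the 28 genes, 10 were also higher in IU, against 1.45 expected of independent lists, and 26 had a positive fold change there. The labels do not say whether both pieces came from the same animals, which would raise this overlap without any effect of mating.

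**Figure D2:**
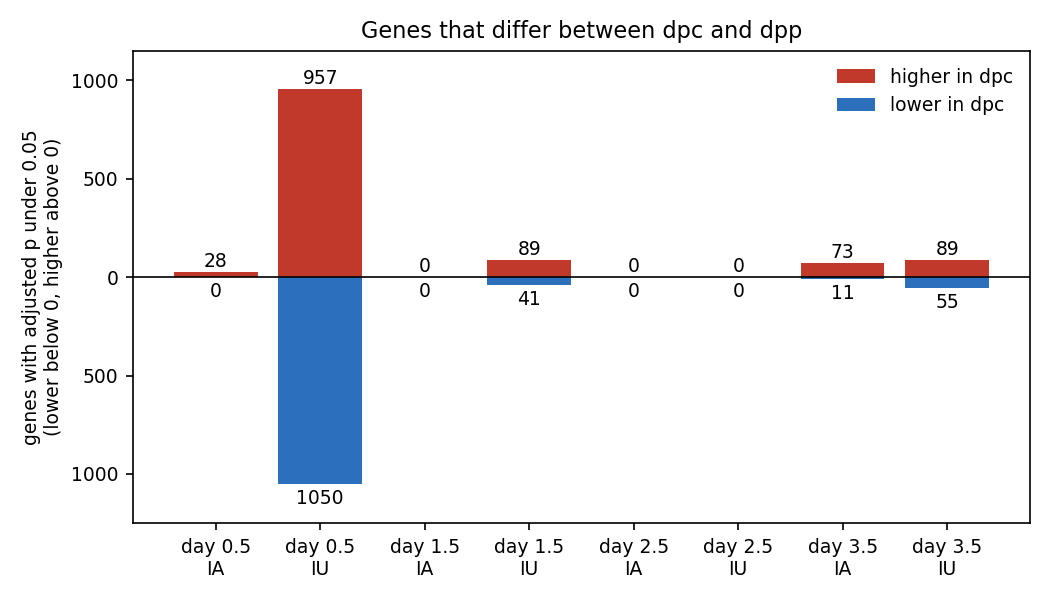
Bars give the number of genes with an adjusted p under 0.05 between dpc and dpp for each day and region (upward, higher in dpc; downward, lower in dpc), from edgeR on 3 libraries per group. IU at day 0.5 has 957 genes higher and 1050 lower, and no other bar passes 89 genes.

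Whether the response to fertile mating differed between regions was tested as an interaction. At day 0.5 the change from dpp to dpc was more positive in IU than in IA for 263 genes and more negative for 279, 542 in all (2563 at an unadjusted p under 0.05). Hmox1 differed by 3.22 ± 0.30 (adjusted p = 1.78e-08): in IA it stood at 39.9 ± 14.7 TPM in dpc and 36.3 ± 3.30 TPM in dpp. Prss28 differed by 6.27 ± 1.10 and Rbp7, a retinol binding protein gene, by 2.87 ± 0.55. In the other direction Adamts16 differed by −3.40 ± 0.41, Kcne1 by −3.08 ± 0.67 and Myo3b, a myosin gene of stereocilia, by −2.52 ± 0.33. Immediate early genes were more positive in IU for 6 of 16 (10 adjusted over the list alone, list adjusted p = 2.29e-14, adjusted p = 0.00544 with an estimated correlation), Atf3 by 2.18 ± 0.27. Glycolysis genes were so for 13 of 23 (15 more positive and 1 more negative adjusted over the list alone, list adjusted p = 2.0e-15, adjusted p = 0.0521 with an estimated correlation), Slc16a3 by 1.66 ± 0.28. Antioxidant enzymes were so for 4 of 22 (7 adjusted over the list alone, list adjusted p = 6.84e-08, adjusted p = 0.141 with an estimated correlation). The count was 356 without 0.5 dpp IA replicate 3 and 94 when only the 12 libraries compared were fitted.

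**Figure D3:**
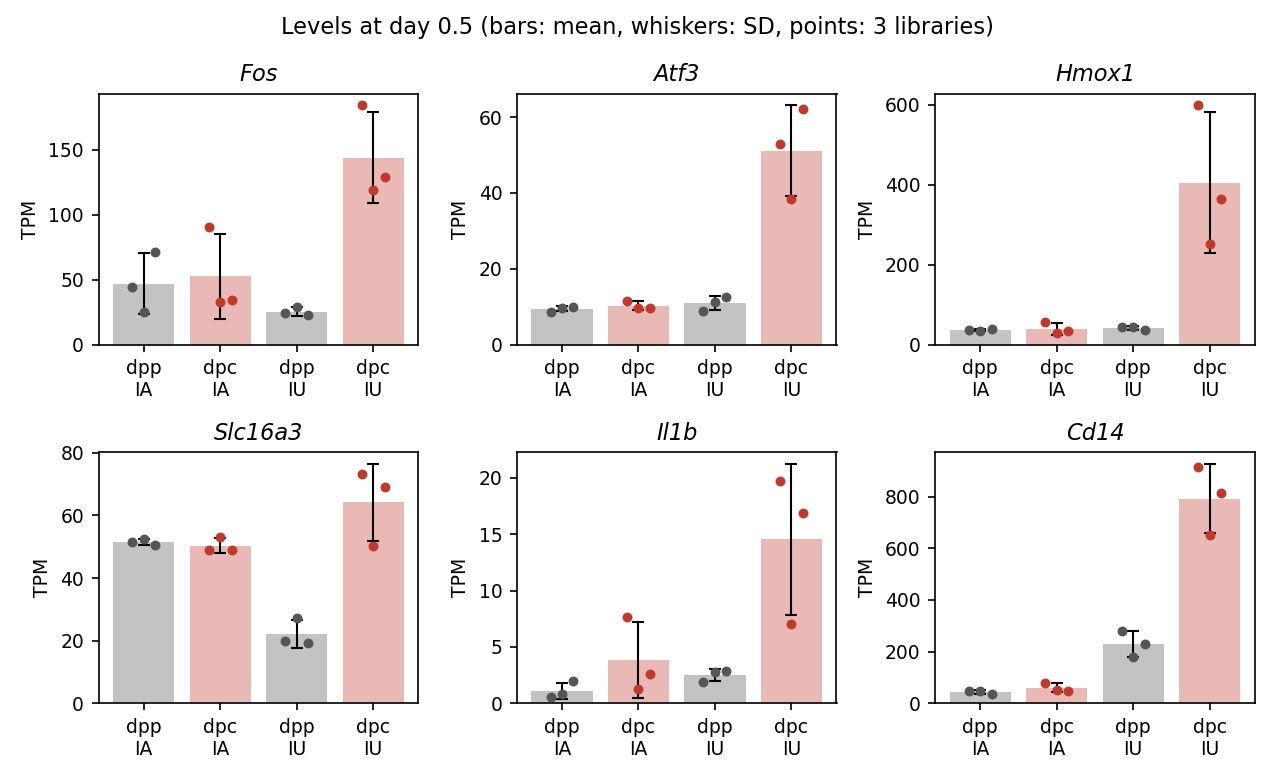
Bars are mean TPM at day 0.5 in dpp and dpc of each region, whiskers the SD and points the 3 libraries, for 6 genes. Fos, Atf3, Hmox1, Slc16a3, Il1b and Cd14 stand higher in dpc than in dpp in IU, Hmox1 at 405 against 41.6 TPM.

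At day 1.5 in IU, Ptgs2 and Fos, both higher in dpc at day 0.5, were lower: Ptgs2 stood at 9.26 ± 1.26 TPM in dpc and 27.1 ± 7.28 TPM in dpp (−1.61 ± 0.32, adjusted p = 0.00677) and Fos at 10.8 ± 0.68 TPM against 24.6 ± 8.28 TPM (−1.25 ± 0.31, adjusted p = 0.0432). Lower too was Sh2d4b, which encodes an SH2 domain protein (−1.14 ± 0.17). Npy2r, a receptor for neuropeptide Y, was higher (2.73 ± 0.41, adjusted p = 0.000641), with 6.02, 40.7 and 14.3 TPM in the 3 dpc libraries and 2.98 ± 1.61 TPM in dpp. Also higher were Tsku, which encodes a secreted Wnt inhibitor (1.90 ± 0.30), and Acaca, the rate-limiting enzyme of fatty acid synthesis (0.80 ± 0.16). Without 1.5 dpc replicate 2 both lost their calls, at 0.88 and 0.33. That library held 75.8 TPM of the fat cell hormone gene Adipoq, against 0 and 0.579 TPM in the other libraries of its group and 0.230, 21.8 and 0 TPM in dpp. Adipocyte markers had positive fold changes for 10 of 10, with 0 called (list adjusted p = 0.249). Cell cycle genes had positive fold changes for 23 of 26, with 0 called (6 adjusted over the list alone, list adjusted p = 5.23e-07, adjusted p = 0.74 with an estimated correlation). Glycolysis genes were lower for 1 of 23 (7 adjusted over the list alone, list adjusted p = 5.23e-07, adjusted p = 0.74 with an estimated correlation), Aldoc by −0.67 ± 0.12. Immediate early genes were lower for 1 of 16 (3 adjusted over the list alone, list adjusted p = 0.00421, adjusted p = 0.74 with an estimated correlation). In all 89 genes were higher and 41 lower (1859 at an unadjusted p under 0.05).

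The count at day 1.5 in IU was 267 without 1.5 dpc replicate 1, 10 without 1.5 dpc replicate 2, 16 without 1.5 dpp replicate 1, 34 without 1.5 dpp replicate 2 and 0 when only the 6 libraries compared were fitted. Of the genes just named only Npy2r and Sh2d4b passed without each single library in turn. By limma on log2(TPM + 1) it was 241 and by DESeq2 222.

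The difference between the mating changes of day 1.5 and day 0.5 was tested in a contrast added after these counts had been seen. For genes that rose at day 0.5 it is negative even without a fall at day 1.5, so it does not test a reversal. In IU the change from dpp to dpc was more positive at day 1.5 than at day 0.5 for 438 genes and more negative for 416. Immediate early genes were more negative for 10 of 16 (11 adjusted over the list alone, list adjusted p = 1.14e-18, adjusted p = 0.000813 with an estimated correlation), Fosb by −5.03 ± 0.62 and Atf3 by −2.44 ± 0.27. Glycolysis genes were more negative for 15 of 23 (16 more negative and 1 more positive adjusted over the list alone, list adjusted p = 2.39e-18, adjusted p = 0.0255 with an estimated correlation), Slc16a3 by −2.08 ± 0.28. Without 1.5 dpc IU replicate 2 the count was 524, and on the 12 libraries compared alone 469.

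In IA at day 1.5, edgeR called 0 genes between dpc and dpp (1545 at an unadjusted p under 0.05), limma 0 on either pseudocount and DESeq2 32. Of 40 lists, 9 passed the list test there, and 3 in IA and 10 in IU at day 2.5, but 0 with an estimated correlation. In IA at day 1.5, endothelial markers had positive fold changes for 13 of 13 (8 higher adjusted over the list alone, list adjusted p = 5.52e-13, adjusted p = 0.282 with an estimated correlation), with a median of 0.62, and of 0.43 without 1.5 dpc replicate 1. Cell cycle genes had a positive one for 1 of 26 (0 called, list adjusted p = 1.75e-09, adjusted p = 0.282 with an estimated correlation). At day 2.5 the smallest list p was that of endothelial markers in IA, with positive fold changes for 2 of 13 (list adjusted p = 0.00016, adjusted p = 0.969 with an estimated correlation). In IU it was that of pyruvate entry and the TCA cycle, with positive ones for 1 of 25 (list adjusted p = 5.06e-06, adjusted p = 0.852 with an estimated correlation). The count in IA at day 1.5 was 2 without 1.5 dpc replicate 1, 8 without 1.5 dpp replicate 2 and 1 without 1.5 dpp replicate 3. At day 2.5, edgeR called 0 genes in IA (745 at an unadjusted p under 0.05; limma 0, DESeq2 2) and 0 in IU (1904 at an unadjusted p under 0.05; limma 0 on log2(TPM + 1) and 1 on log2(TPM + 0.1), DESeq2 25). Without any difference, a share of 0.05 of the 18443 tested genes would be expected at an unadjusted p under 0.05. The 745 genes of IA at day 2.5 lie below that share. In IU 101 genes were called without 2.5 dpc replicate 2, 6 without 2.5 dpp replicate 1 and 1 without 2.5 dpp replicate 2, and in IA 5 when only the 6 libraries compared were fitted. No interaction of region and mating was called by edgeR at day 1.5 (955 at an unadjusted p under 0.05; limma 1 and 0, DESeq2 23), day 2.5 (874; limma 0, DESeq2 0) or day 3.5 (1844; limma 0, DESeq2 112). Of the lists, 6 of 40 passed for the interaction at day 1.5, and cell cycle genes alone did so with an estimated correlation. Their change from dpp to dpc was more positive in IU for 26 of 26, with 0 called (12 adjusted over the list alone, median 0.91, list adjusted p = 1.86e-21, adjusted p = 0.0325 with an estimated correlation). Leaving out each of the 12 libraries in turn gave list adjusted p of 4.28e-12 or less, while with an estimated correlation adjusted p ran from 0.00213 to 0.307 and the call was lost in 7 of 12. For the interaction at day 1.5 the count of genes was 61 without 1.5 dpc IU replicate 1, and at day 3.5 it was 136 without 3.5 dpc IA replicate 1 and 187 without 3.5 dpc IA replicate 3.

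At day 3.5, of 14 genes of the circadian clock, a list written after some of them had been seen among the called genes, 8 were called in IA and 5 in IU. In IA, Bmal1 (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126), the core activator of the clock, stood at 9.39 ± 0.89 TPM in dpc and 18.1 ± 1.36 TPM in dpp (−0.98 ± 0.14, adjusted p = 0.000315). Npas2, which pairs with it, fell by 0.97 on the log2 scale (SE 0.17). Hlf, an output transcription factor of the clock, rose by 1.86 ± 0.29 and the repressor gene Ciart by 1.82 ± 0.28. In IU, Bmal1 was lower (−0.63 ± 0.13, adjusted p = 0.0252) and the output gene Dbp and the period gene Per3 higher (1.28 ± 0.26 and 1.07 ± 0.22). Unc5cl, a gene of NF-kB signalling in mucosa, stood at 33.3 ± 6.75 TPM against 122 ± 12.7 TPM in IU (−1.94 ± 0.29, adjusted p = 0.00122), and Stat5a, a transducer of prolactin and cytokine signals, differed by −0.85 ± 0.21. Genes of the unfolded protein response were lower in IU for 1 of 20 (12 adjusted over the list alone, list adjusted p = 5.42e-07, adjusted p = 0.921 with an estimated correlation), Pdia3 by −0.48 ± 0.12.

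Hox patterning genes were higher in IA at 3.5 dpc for 4 of 18 (10 adjusted over the list alone, list adjusted p = 0.00017, adjusted p = 0.439 with an estimated correlation). Progesterone-associated genes were higher for 4 of 19 (6 adjusted over the list alone, list adjusted p = 4.66e-05, adjusted p = 0.332 with an estimated correlation), among them the hedgehog ligand gene Ihh (3.52 ± 0.72), and endothelial markers were for 1 of 13 (8 adjusted over the list alone, list adjusted p = 1.15e-08, adjusted p = 0.439 with an estimated correlation). All 3 lists lost every call without 3.5 dpc replicate 2, the IA library that held transcripts of the IU end. Ihh stood at 31.8 TPM there and at 0.976 and 1.37 TPM in the other libraries of the group. Without it Hoxa9 changed sign from 5.00 ± 1.04 to −0.21 and Wnt7a, a Wnt ligand of the uterine epithelium, from 3.59 ± 0.77 to −0.56, while Bmal1, Npas2, Hlf and Ciart kept their calls. On the 6 libraries compared alone only Bmal1 of these kept its call.

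In all, 73 genes were higher and 11 lower in IA at day 3.5 (1963 at an unadjusted p under 0.05), and 89 higher and 55 lower in IU (3001). In IA the count was 310 without 3.5 dpc replicate 1, 8 without 3.5 dpc replicate 2, 440 without 3.5 dpc replicate 3, 6 without 3.5 dpp replicate 1, 6 without 3.5 dpp replicate 2, 7 without 3.5 dpp replicate 3 and 5 when only the 6 libraries compared were fitted. By limma it was 14 on log2(TPM + 1) and 18 on log2(TPM + 0.1) and by DESeq2 309. In IU it was 4 without 3.5 dpc replicate 1, 13 without 3.5 dpc replicate 2, 32 without 3.5 dpc replicate 3, 1 without 3.5 dpp replicate 1, 77 without 3.5 dpp replicate 2 and 2 without 3.5 dpp replicate 3. Of the genes named in IU only Unc5cl passed in each of these. On the 6 libraries compared alone 1526 genes were called in IU, by limma on log2(TPM + 1) 297 and by DESeq2 498. Between regions, the higher genes Dbp, Nr1d2 and Tef were shared (3 against 0.352 expected of independent lists), and the lower genes Bmal1 and Lcorl (2 against 0.0328). If both pieces came from the same animals, which the labels do not state, these overlaps would rise without any effect of mating. Without 3.5 dpc IA replicate 2 only Tef and Bmal1 were shared, of 5 genes higher and 3 lower in IA. Dbp and Nr1d2 went from 1.2 ± 0.26 and 0.55 ± 0.12 in IA to 1.29 and 0.59 without it (adjusted p = 0.0865 for both), so their calls ended without a smaller fold change. Of the 73 genes higher in IA, 41 had a positive fold change in IU, and of the 11 lower, 10 had a negative one.

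The second set of comparisons asks how the 2 ends of the oviduct differ. Ciliated cells marked IA: multiciliated epithelium markers were lower in IU for 24 of 24 in dpc over the 4 days (median −3.04, list adjusted p = 1.52e-14, adjusted p = 0.463 with an estimated correlation). Ciliogenesis regulators were lower for 13 of 13 (median −2.55, list adjusted p = 1.39e-06, adjusted p = 0.463 with an estimated correlation). Foxj1, the master regulator of motile cilia, differed by −2.95 ± 0.10 and the axonemal gene Tekt2 by −2.23 ± 0.07. Muscle and connective tissue marked IU, with smooth muscle markers higher for 15 of 16 and lower for 1 (list adjusted p = 0.000466, adjusted p = 0.525 with an estimated correlation), Myl9 by 3.05 ± 0.23. The exception was the filament gene Synm (−2.94 ± 0.13). Stromal fibroblast markers were higher for 14 of 14 (list adjusted p = 5.53e-05, adjusted p = 0.501 with an estimated correlation). Endothelial markers were higher for 13 of 13 (list adjusted p = 2.43e-05, adjusted p = 0.463 with an estimated correlation). Adjusted over each list alone, all these counts were the same.

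Patterning and immune genes also followed region. Hox genes were higher in IU for 15 of 18 and lower for 3 (list adjusted p = 0.00184, adjusted p = 0.463 with an estimated correlation). At 0.5 dpc Hoxa9 stood at 19.3 ± 2.20 TPM in IU and 0.0194 ± 0.0174 TPM in IA, and one of the 3 lower genes was Hoxd3 (−2.69 ± 0.19). Macrophage markers were higher for 18 of 18 (list adjusted p = 1.05e-05, adjusted p = 0.463 with an estimated correlation), the receptor gene Csf1r by 1.43 ± 0.08. Interferon response genes were higher for 23 of 25 and lower for 1 (list adjusted p = 5.53e-05, adjusted p = 0.525 with an estimated correlation). The lower one was Usp18, a brake on interferon signalling (−2.10 ± 0.09). Prostaglandin genes were higher for 14 of 18 and lower for 3 (list adjusted p = 0.00715, adjusted p = 0.463 with an estimated correlation), among them Ptgs2 (5.89 ± 0.22). The growth factor gene Ereg was among those lower in IU (−5.42 ± 0.31). Adjusted over each list alone, all these counts were the same.

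In dpc 8277 genes were higher in IU and 6844 lower, 15121 of 18443, and in dpp 8149 and 6961, 15110 in all. The lists divided alike in dpp: multiciliated markers were lower for 24 of 24 (list adjusted p = 3.21e-14, adjusted p = 0.456 with an estimated correlation). Ciliogenesis regulators were lower there for 13 of 13 (list adjusted p = 1.61e-06, adjusted p = 0.456 with an estimated correlation). Smooth muscle markers were higher for 15 and lower for 1 of 16 (list adjusted p = 0.000176, adjusted p = 0.486 with an estimated correlation), and Hox genes were higher for 15 and lower for 3 of 18 (list adjusted p = 0.00162, adjusted p = 0.456 with an estimated correlation). In estrus 5210 genes were higher in IU and 5069 lower among 17136 in both deposited tables, and 6293 were called when the 6 estrus libraries were fitted alone. There multiciliated markers were lower for 24 of 24 (list adjusted p = 3.37e-21, adjusted p = 0.329 with an estimated correlation), Foxj1 by −3.22 ± 0.20. Ciliogenesis regulators were lower for 12 of 13 (list adjusted p = 1.54e-07, adjusted p = 0.188 with an estimated correlation). Smooth muscle markers were higher for 14 and lower for 1 of 16 (list adjusted p = 0.00347, adjusted p = 0.598 with an estimated correlation) and Hox genes were higher for 15 and lower for 3 of 18 (list adjusted p = 0.000806, adjusted p = 0.486 with an estimated correlation). Adjusted over each list alone, these counts were the same in dpp, and in estrus they were the same except for ciliogenesis regulators (13 lower) and smooth muscle markers (15 higher and 1 lower).

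**Figure D4:**
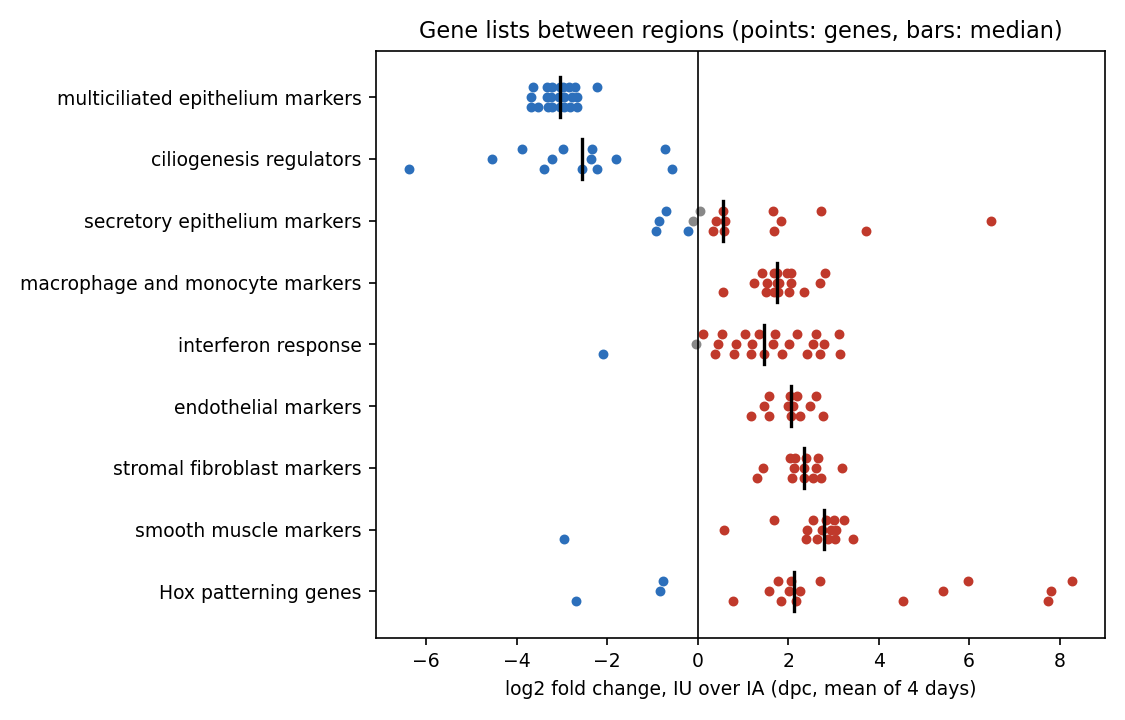
Each point is a gene of the list named on the left, placed by its log2 fold change of IU over IA in dpc, averaged over 4 days with 3 libraries per group, and bars mark the list medians. Multiciliated and ciliogenesis genes lie left of 0, with medians of −3.04 and −2.55, and 15 of 16 smooth muscle genes lie right of it.

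The third set of comparisons follows the oviduct from day to day after fertile mating. In IA from 0.5 to 1.5 dpc, genes of the unfolded protein response, which raise the folding capacity of the endoplasmic reticulum, were lower for 18 of 20 (18 adjusted over the list alone, list adjusted p = 2.4e-12, adjusted p = 0.585 with an estimated correlation). The folding enzyme gene Pdia6 went from 1144 ± 204 TPM to 350 ± 24.3 TPM (−1.80 ± 0.15, adjusted p = 2.19e-11). Cholesterol synthesis genes were lower for 19 of 22 (20 adjusted over the list alone, list adjusted p = 1.15e-08, adjusted p = 0.585 with an estimated correlation). Interferon response genes were lower for 19 of 25 and higher for 1 (20 and 1 adjusted over the list alone, list adjusted p = 2.83e-07, adjusted p = 0.585 with an estimated correlation), Isg15 by −2.28 ± 0.33. Oxidative phosphorylation genes were lower for 26 of 31 (27 adjusted over the list alone, list adjusted p = 2.05e-12, adjusted p = 0.585 with an estimated correlation). Glycolysis genes were lower for 15 of 23 and higher for 2 (16 and 2 adjusted over the list alone, list adjusted p = 1.06e-05, adjusted p = 0.585 with an estimated correlation), the lactate dehydrogenase gene Ldha by −1.84 ± 0.14. Multiciliated markers were higher for 15 of 24 (17 adjusted over the list alone, list adjusted p = 1.78e-05, adjusted p = 0.729 with an estimated correlation), Tekt2 by 0.77 ± 0.13. Higher too was the glucocorticoid- and progesterone-induced gene Tsc22d3 (1.19 ± 0.12).

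In all 3039 genes were higher and 4105 lower at 1.5 dpc in IA, and 3804 and 3298 under median-ratio scaling, a step in higher calls from 42.5% to 53.6%. The labels place animals of day 0.5 with males at a later evening hour than those of the other days, so day and hour of mating change together in this step, in IU too. On the 6 libraries compared alone 4038 genes were called. In dpp, 96.8% of the 7144 genes had the same sign.

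In IA from 1.5 to 2.5 dpc, markers of endothelium were lower for 11 of 13 (12 adjusted over the list alone, list adjusted p = 8.96e-19, adjusted p = 0.0781 with an estimated correlation). Markers of stromal fibroblasts were lower for 13 of 14 (13 adjusted over the list alone, list adjusted p = 9.67e-15, adjusted p = 0.176 with an estimated correlation), and of smooth muscle for 11 of 16 (13 adjusted over the list alone, list adjusted p = 3.05e-13, adjusted p = 0.176 with an estimated correlation), Myh11, the smooth muscle myosin, by −2.54 ± 0.52. Cell cycle genes were lower for 7 of 26 (11 adjusted over the list alone, list adjusted p = 4.4e-07, adjusted p = 0.226 with an estimated correlation), Mki67 by −2.90 ± 0.45. Among all genes 236 were higher and 627 lower (83 and 691 under median-ratio scaling, 10.7% higher in place of 27.3%). Each of these calls was lost without 1.5 dpc replicate 1, when 0 genes were called, and that library held 282 TPM of Myh11 against 78.1 and 77.4 TPM in the others of its group. The count was 244 without 2.5 dpc replicate 1, 482 without 2.5 dpc replicate 2, 245 without 2.5 dpc replicate 3 and 27 on the 6 libraries compared alone, and by limma on log2(TPM + 1) it was 442. The same sign was found in dpp for 93.3% of the 863 genes.

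In IA from 2.5 to 3.5 dpc, endothelial markers were higher for 10 of 13 (12 adjusted over the list alone, list adjusted p = 3.15e-20, adjusted p = 0.0553 with an estimated correlation). Pecam1, an endothelial junction gene, stood at 14.1 ± 4.03 TPM against 4.97 ± 0.45 TPM (1.44 ± 0.25, adjusted p = 0.00207). Smooth muscle markers were higher for 7 of 16 (12 adjusted over the list alone, list adjusted p = 3.71e-07, adjusted p = 0.421 with an estimated correlation). Stromal markers were higher for 3 of 14 (13 adjusted over the list alone, list adjusted p = 6.5e-09, adjusted p = 0.375 with an estimated correlation) and Hox genes were for 6 of 18 (9 adjusted over the list alone, list adjusted p = 0.00365, adjusted p = 0.534 with an estimated correlation). The matrix protease gene Adamts4 was lower (−1.44 ± 0.27). Without 3.5 dpc replicate 2, the library with transcripts of the IU end, 50 genes were called, endothelial markers for 4 of 13 and smooth muscle, stromal and Hox genes for 0. In all 310 genes were higher and 139 lower (443 and 69 under median-ratio scaling, 86.5% higher in place of 69.0%). The count was 53 without 2.5 dpc replicate 1, 175 without 2.5 dpc replicate 2, 72 without 2.5 dpc replicate 3, 947 without 3.5 dpc replicate 3 and 0 on the 6 libraries compared alone. Limma gave 140 on log2(TPM + 1) and 209 on log2(TPM + 0.1) and DESeq2 957. In dpp 65.3% of the 449 genes had the same sign, and edgeR called 0 genes between 2.5 and 3.5 dpp.

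In IU from 0.5 to 1.5 dpc, interferon response genes were lower for 25 of 25 (25 adjusted over the list alone, list adjusted p = 9.06e-17, adjusted p = 0.124 with an estimated correlation). Cytokines and chemokines were lower for 16 of 25 (16 adjusted over the list alone, list adjusted p = 7.16e-09, adjusted p = 0.124 with an estimated correlation), the neutrophil attractant gene Cxcl2 by −7.59 ± 1.06 from 26.0 ± 4.19 TPM to 0.139 ± 0.0635 TPM. NF-kB genes were lower for 14 of 22 and higher for 1 (16 and 2 adjusted over the list alone, list adjusted p = 1.67e-08, adjusted p = 0.131 with an estimated correlation). Immediate early genes were lower for 11 of 16 and higher for 1 (11 and 1 adjusted over the list alone, list adjusted p = 1.26e-09, adjusted p = 0.0553 with an estimated correlation), Fos by −3.82 ± 0.33. Glycolysis genes were lower for 17 of 23 and higher for 2 (17 and 3 adjusted over the list alone, list adjusted p = 3.15e-11, adjusted p = 0.124 with an estimated correlation), Slc16a3 by −2.37 ± 0.20. Unfolded protein response genes were lower for 18 of 20 (20 adjusted over the list alone, list adjusted p = 4.45e-08, adjusted p = 0.378 with an estimated correlation), Xbp1, a transcription factor of that response, by −1.30 ± 0.14.

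Progesterone-associated genes were higher at 1.5 dpc in IU for 10 of 19 and lower for 1 (10 and 1 adjusted over the list alone, list adjusted p = 0.00504, adjusted p = 0.332 with an estimated correlation). Ihh went from 5.50 ± 1.53 TPM to 152 ± 52.5 TPM (4.71 ± 0.62, adjusted p = 1.57e-07), and the steroid receptor co-chaperone gene Fkbp5 rose by 2.31 ± 0.21. Multiciliated markers were higher for 20 of 24 (23 adjusted over the list alone, list adjusted p = 1.29e-06, adjusted p = 0.543 with an estimated correlation), Hydin, a gene of the ciliary central pair, by 1.34 ± 0.24. Kcnj16 had the largest fall of the called genes, to 0.0248 ± 0.0217 TPM from 22.9 ± 5.65 TPM (−9.82 ± 0.78). Adipocyte markers were higher for 7 of 10 (9 adjusted over the list alone), while the list test gave adjusted p = 0.361. All 7 calls were lost without 1.5 dpc replicate 2, the library with 75.8 TPM of Adipoq. Without that library 3343 genes were higher and 2421 lower, multiciliated markers higher for 16 and progesterone-associated genes higher for 7 and lower for 1. With all libraries 3979 were higher and 2955 lower, and 90.0% of these 6934 had the same sign in dpp.

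In IU from 1.5 to 2.5 dpc, oestrogen-associated genes were lower for 8 of 16 (11 adjusted over the list alone, list adjusted p = 4.92e-05, adjusted p = 0.256 with an estimated correlation), the gap junction gene Gjb2 by −1.99 ± 0.27. Antimicrobial and mucosal defence genes were lower for 4 of 16 (4 lower and 1 higher adjusted over the list alone, list adjusted p = 0.0339, adjusted p = 0.654 with an estimated correlation). The siderophore-binding Lcn2 went from 484 ± 485 TPM to 61.6 ± 4.93 TPM (−2.92 ± 0.48, adjusted p = 0.000189) and lactoferrin, Ltf, from 4984 ± 795 TPM to 2444 ± 201 TPM (−1.0 ± 0.20). Glycolysis genes were lower for 7 of 23 (12 adjusted over the list alone, list adjusted p = 0.00012, adjusted p = 0.654 with an estimated correlation), while Tyms, which makes thymidylate for DNA, was higher (0.91 ± 0.14). Adipocyte markers were lower for 5 of 10 (10 adjusted over the list alone, list adjusted p = 0.00817, adjusted p = 0.836 with an estimated correlation), and for 0 without 1.5 dpc replicate 2. Without that library 709 genes were higher and 887 lower, oestrogen-associated genes lower for 8, antimicrobial genes for 4 and glycolysis genes for 10. In all 521 genes were higher and 727 lower. The count was 253 without 1.5 dpc replicate 1, 726 without 1.5 dpc replicate 3, 466 without 2.5 dpc replicate 1, 2180 without 2.5 dpc replicate 2, 327 without 2.5 dpc replicate 3 and 0 on the 6 libraries compared alone. In the last of these, Gjb2, Lcn2, Ltf and Tyms lost their calls. In dpp 90.1% of the 1248 genes had the same sign.

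In IU from 2.5 to 3.5 dpc, the desmosomal cadherin gene Dsg3 was higher, at 7.07 ± 0.59 TPM against 1.57 ± 0.49 TPM (2.11 ± 0.20, adjusted p = 5.5e-09), and the tight junction gene Cldn4 rose by 1.6 ± 0.19. Il6 fell from 7.89 ± 1.98 TPM to 0.688 ± 0.1 TPM (−3.59 ± 0.70, adjusted p = 0.000988) and Adamts16 by 2.96 on the log2 scale (SE 0.30). Unfolded protein response genes were lower for 10 of 20 (14 adjusted over the list alone, list adjusted p = 2.78e-10, adjusted p = 0.933 with an estimated correlation), the chaperone gene Calr by −0.81 ± 0.13. Oxidative phosphorylation genes were lower for 11 of 31 (13 adjusted over the list alone, list adjusted p = 6.35e-06, adjusted p = 0.933 with an estimated correlation). In all 1138 genes were higher and 996 lower, and 85.8% of them had the same sign in dpp. The count was 925 without 2.5 dpc replicate 1, 770 without 2.5 dpc replicate 3, 1062 without 3.5 dpc replicate 1 and 1373 without 3.5 dpc replicate 2.

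**Figure D5:**
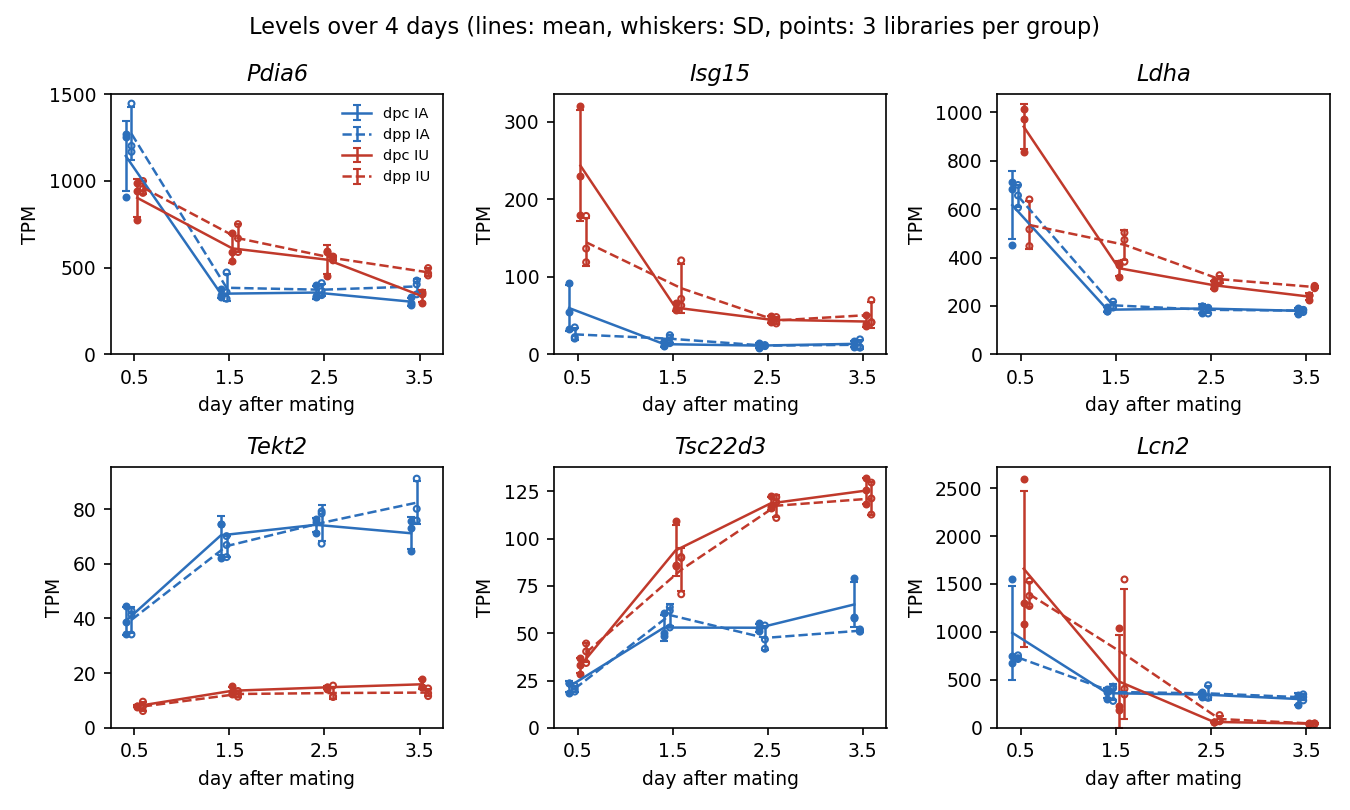
Lines give mean TPM over the 4 days after mating for dpc and dpp in IA and IU, whiskers the SD and points the 3 libraries per group, for 6 genes. Pdia6, Isg15 and Ldha stand highest at day 0.5, and Tekt2 and Tsc22d3 rise from day 0.5 to day 1.5. The mean of Lcn2 in IU of dpc goes from 484 TPM at day 1.5 to 61.6 TPM at day 2.5. Its SD at day 1.5 is about as large as that mean.

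Levels at 0.5 dpc are set beside those in estrus without a test. In IU, Fos stood at 17.1 ± 3.43 TPM in estrus, Hmox1 at 32.5 ± 8.05 TPM, Slc16a3 at 8.08 ± 1.56 TPM and Il1b at 1.65 ± 0.37 TPM, each below its 0.5 dpc mean. In IA, Fos stood at 27.4 ± 8.62 TPM and Hmox1 at 22.6 ± 6.09 TPM in estrus. Pgr in IU spread more between the estrus libraries, with 212, 65.2 and 87.3 TPM, than between those of 0.5 dpc (44.0 ± 2.30 TPM).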

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

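The tests of delay and leukocytes and leaving libraries out of the cell cycle list were chosen after the results were seen. So was the contrast between days 1.5 and 0.5, and with it its count of splits. Counts over other splits of the samples were otherwise planned.

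At day 0.5 the change from dpp to dpc differed between IU and IA, by a test of the difference itself, for 542 genes. The largest differences picked by the naming rule were Prss28 (6.27), Hmox1 (3.22), Chct1 (2.97), Rbp7 (2.87) and Klk1b11 (2.66) upward, and Adamts16 (−3.40), Rnf223 (−3.21), Kcne1 (−3.08), Siglech (−2.78) and Myo3b (−2.52) downward, on the log2 scale. The median difference was 0.85 for immediate early genes and 0.61 for genes of glycolysis and lactate export (list tests with an estimated correlation, adjusted p = 0.00544 and adjusted p = 0.0521, so the call of the second list was lost). Between day 1.5 and day 0.5 in IU the change differed for 854 genes. At day 1.5 the median difference between IU and IA was 0.91 for cell cycle genes, by the list test (adjusted p = 0.0325 with an estimated correlation, and up to 0.307 when 1 library was left out), while 0 of them were called.

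Of 100 splits of the 12 libraries of day 0.5, 9 called at least 542 genes, the real one included, and the highest of the others called 3077, so this count of splits does not exclude chance. Of the 8 others, 6 kept the IU libraries in their mating groups, the one with 3077 genes among them, and so hold the mating change of IU. The remaining 2 exchanged libraries in both regions and called 1043 and 619 genes. Splits far above the real count point to a structure of the samples, of which that retained change is a part, and no further source was tested. For the contrast of days in IU, 3 of 100 splits called at least 854 genes, the real one included, and the highest of the others called 1064. This share is under 0.05, but the splits could exchange libraries on both days. It therefore speaks to a mating change on either day and cannot exclude chance for a difference between the days. Both others as large kept the day 0.5 libraries in their mating groups and exchanged only those of day 1.5. The contrast was also chosen because the counts of the 2 days had been seen to differ.

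Immediate early genes stood higher at 0.5 dpc in IU for 9 of 16 and glycolysis genes for 15 of 23, with 1 lower. With an estimated correlation the list tests gave adjusted p = 0.0028 and adjusted p = 0.146, so the call of glycolysis was lost. A delay in handling the whole animal could raise immediate early genes in both regions. Their median change in IA was 0.0618 of that in IU. This argues against such a delay only if IA responds to it as readily as IU, which was not measured. The difference between regions had also been seen before this test was chosen, so the test is no independent support. Leukocytes entering the tissue would bring their markers along. The median excess in IU over IA of neutrophil and macrophage markers was −0.26, against 0.61 for glycolysis genes. The marker median, over 34 genes, had a 95% bootstrap interval of −0.35 to −0.0827, which resampled genes and not libraries. Some of these markers rose in IU itself and in IA too. The excess therefore cannot decide on leukocytes, which stay open. A delay confined to the IU pieces of one group was not tested and stays open. Nor was a different hour of collection tested here, and 6 of 14 clock genes were called in IU at day 0.5. A response of the IU end to fertile mating may be a candidate explanation.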

How the results depend on the processing

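The TPM filter, limma on log2(TPM + 1) and DESeq2 were alternatives chosen after the files were seen, as was leaving single libraries out of the gene lists. The cause of the changes below was not tested. Fits on fewer libraries have less information, but some of their counts rose where others fell.

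Without a filter, with the TPM filter and with median-ratio scaling, each count of called genes stayed within 1.5 times. With limma on log2(TPM + 1), counts moved to 241 (1.5 dpc against dpp, IU), 14 (3.5, IA), 297 (3.5, IU), 1 (difference between regions, day 1.5), 442 (2.5 against 1.5 dpc, IA) and 140 (3.5 against 2.5 dpc, IA). On log2(TPM + 0.1) they moved to 46 (0.5, IA), 1 (2.5, IU), 18 (3.5, IA) and 209 (3.5 against 2.5 dpc, IA).

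With DESeq2, counts moved to 112 (0.5, IA), 32 (1.5, IA), 222 (1.5, IU), 2 (2.5, IA), 25 (2.5, IU), 309 (3.5, IA), 498 (3.5, IU), 23 and 112 (difference between regions, days 1.5 and 3.5) and 957 (3.5 against 2.5 dpc, IA).

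Fitted on only the groups compared, counts moved to 0 (0.5, IA), 1183 (0.5, IU), 0 (1.5, IU), 5 (2.5, IA), 5 (3.5, IA), 1526 (3.5, IU), 94 and 8 (difference between regions, days 0.5 and 3.5), 6293 (regions in estrus), 4038, 27 and 0 (successive days, IA), 0 (2.5 against 1.5 dpc, IU) and 469 (day 1.5 against day 0.5 of the mating change, IU). For the 4 counts of 0 the fit on all libraries by edgeR called 28, 130, 449 and 1248.

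The labels do not say that a replicate number marks 1 animal, and IA and IU libraries of the same number did not all deviate together: of 24 pairs, 17 correlated over 0.1 (median 0.26) and 18 correlated best with their own number, a hint of pairing from the data in some groups. As pairing was not established for all groups, libraries were fitted without a block. At day 1.5 every pair of IA and IU correlated best with its own number (0.15 to 0.50). The list tests and splits of that day took no account of this. With a replicate block, counts moved to 35 (3.5, IA), 79 (3.5, IU), 1 (difference between regions, day 1.5) and 246 (3.5 against 2.5 dpc, IA). For dpc against dpp and for successive days, the block joined libraries of different matings or days by number alone. Between dpc and dpp, 5 of 24 pairs of the same number correlated over 0.1 (median −0.14) and 3 correlated best with their own number. Region counts with it were 15180 (dpc), 15058 (dpp) and 10362 (estrus), and that for the difference between regions at day 0.5 was 634.

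Leaving out 1 library gave these lowest and highest counts. For dpc against dpp: 5 to 39 (0.5, IA), 1397 to 1724 (0.5, IU), 0 to 8 (1.5, IA), 10 to 267 (1.5, IU), 0 to 0 (2.5, IA), 0 to 101 (2.5, IU), 6 to 440 (3.5, IA) and 1 to 77 (3.5, IU). For differences between regions: 356 to 699, 0 to 61, 0 to 0 and 0 to 187 on the 4 days. For regions: 14944 to 15085 (dpc), 14960 to 15100 (dpp) and 9309 to 10133 (estrus). For successive days: 5243 to 7888, 0 to 1198 and 50 to 947 in IA, and 5597 to 6705, 253 to 2180 and 770 to 3088 in IU. For the change between days 0.5 and 1.5 in IU: 524 to 939.

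For 278 named genes in 415 gene comparisons, 6536 of 7215 values kept direction and side of the threshold, 662 lost their call, 11 gained one and 6 changed sign. The 6 did so when 1 library was left out, and over all such fits ranged from −4.86 to 2.32 for Cyp11a1 (day 0.5, IU; 2.32 without 0.5 dpp replicate 1), −0.21 to 6.57 for Hoxa9, −0.21 to 7.29 for Hoxa10 and −0.56 to 4.13 for Wnt7a (day 3.5, IA), −0.12 to 4.22 for Lrp2 (3.5 against 2.5 dpc, IA) and −1.01 to 8.77 for Adipoq (1.5 against 0.5 dpc, IU). The negative values of Hoxa9, Hoxa10, Wnt7a and Lrp2 are those without 3.5 dpc IA replicate 2, and that of Adipoq is without 1.5 dpc IU replicate 2. Of 879 list results 237 passed the threshold, and 5 did with an estimated correlation. Among the 75 past it that were picked for the report, 70 lost it.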

Other observations

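The tests of mixed tissue, exchange, fertile mating and hour of collection were chosen after the results were seen; the counts over other splits of the samples were planned.

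Genes of the IU region appeared in the IA library 3.5 dpc replicate 2. Of 23 genes found only in IU (judged without the 3.5 dpc IA libraries), 100% lay above both other libraries of the group, so tissue of the IU region in the IA piece may be the source. An exchange with an IU library is argued against by the median of 22.89% of the 3.5 dpc IU level (quartiles 20.74% and 23.88%). A response to fertile mating shared by the 3 libraries of the group is argued against too, since replicates 1 and 3 held medians of 0.247% and 0.447% of the IU level, and 3.5 dpp IA libraries 0.188% to 0.243%. Whether fertile mating raised these genes slightly in replicates 1 and 3 stays open: 21.74% and 47.83% of them lay above every 3.5 dpp IA library.

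Clock genes differed between 3.5 dpc and 3.5 dpp for 8 of 14 in IA and 5 of 14 in IU. Of 28 signs (14 genes in 2 regions, a list written after clock genes appeared among the called genes), 27 followed 1 shift of the clock (median −0.665 in the phase of Bmal1), as a different hour of tissue collection could bring about, though the labels give the same time points for dpp and dpc. Both regions may come from the same animals, which the labels do not state, so the 28 signs need not be independent. The sign count was not specific to day 3.5: it was 26 of 28 the same way at day 2.5 (median −0.145, no gene called by edgeR). The opposite way went 17 of 28 at day 1.5 (0.0223) and 23 of 28 at day 0.5 (0.278). Of the 6 genes called in IU at day 0.5, Per1 (log2 fold change 0.80) did not go that way. Tissue of the IU region in the IA piece is argued against, since the median clock change in IA without 3.5 dpc replicate 2 was 1.13 times its value with it. An effect of fertile mating on the clock would give the same signs, is confounded with any difference in hour and stays open, untested.

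For comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. The real count and the highest of the other splits between dpc and dpp were 28 and 1307 at day 0.5 in IA (3 of 10 splits called as many), 2007 and 36 at day 0.5 in IU, 0 and 0 at day 1.5 in IA, 130 and 106 at day 1.5 in IU, 0 and 0 at day 2.5 in IA, 0 and 311 at day 2.5 in IU, 84 and 51 at day 3.5 in IA and 144 and 0 at day 3.5 in IU. These counts of 0 are from edgeR, with 1545 genes at an unadjusted p under 0.05 at day 1.5 in IA, 745 at day 2.5 in IA and 1904 at day 2.5 in IU, and DESeq2 called 32, 2 and 25. The splits with 1307 and 311 genes point to a structure of the samples other than mating. For successive days they were 7144 and 1976, 863 and 12, and 449 and 41 in IA, and 6934 and 69, 1248 and 581, and 2134 and 73 in IU, and for regions in estrus 10279 and 2542 (1 of 10 splits each).

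For regions in dpc and dpp, 1 of 100 splits called as many genes as the real 15121 and 15110, and the highest others called 12298 and 10552, so chance is excluded. For differences between regions of the mating change, the real count of edgeR was 0 at days 1.5, 2.5 and 3.5 (955, 874 and 1844 genes at an unadjusted p under 0.05; DESeq2 23, 0 and 112), which 100 of 100 splits reach, with highest others of 106, 12 and 20.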
